A study of Homo sapiens with 4 samples.

How the data were processed

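RNA of CD8+ T cells was measured on 4 two-colour Agilent arrays. Per the labels, each array held RNA of cells primed in the presence of ILT3-Fc in the Cy3 channel and RNA of cells primed without it in the Cy5 channel. The 4 arrays therefore give 4 pairs of treated and untreated measurements, which were treated as replicates. All arrays had 1 dye orientation, so a dye effect that belongs to a gene stays in its ratio.

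The deposited scanner output held spot intensity on a linear scale, produced with Agilent Feature Extraction 10.5.1.1 and its protocol GE2_105_Dec08, per the file headers. The mean foreground and median local background intensity of each channel were used as deposited. Feature Extraction had also subtracted the background, detrended the signal and normalised the dyes, and it gave a log10 ratio of Cy5 over Cy3 per spot, per the file headers. The authors' deposited value table held the same log10 ratio with the opposite sign, that is Cy3 over Cy5, to within 5e-06 on all 45015 spots of each array, and each column had a median of 0. Its scale, direction and lack of further centring were thus settled by this comparison. Between 9512 and 12794 spots per array were listed with a log10 ratio of exactly 0. The deposited files also carried flags per spot for signal above background, saturation and outliers, per the file headers. The submitters' processing notes name limma without a version.

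Background was corrected with normexp and an offset of 50 on all spots, and each array was normalised with loess (span 0.3) in limma 3.58.1 under R 4.3.3, with weight 0 for control spots and for spots that carried an outlier flag. Saturated spots were kept, but none was present. The ratio was turned to log2 of Cy3 over Cy5, the channel labelled treated over the channel labelled untreated. Replicate spots of a probe were averaged. A probe was tested if it was well above background in at least 1 channel on at least 3 of the 4 arrays, and each gene was represented by its brightest tested probe over both channels and all arrays. This gave 25850 probes and 18969 genes. Ratios of named genes are those of the brightest probe, and other probes of a gene could give smaller ones. Of the 41000 probes, 25398 were named through their accession, 2510 through their symbol and 789 through a synonym in the RefSeq gene table of the assembly GRCh38.p14, and 12303 kept the name in the file. That table was used for names only. Probe positions are those of the files, in the NCBI36 (hg18) build, and no annotation of that build was used here, so exon or UTR positions are not given. For privacy, 131 probes of Y-linked genes and of the X-inactivation transcripts were left out.

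Ratios were tested against 0 with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene is called higher or lower below only where it passed that threshold. Gene lists with at least 3 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01, with adjustment over the 32 lists tested. Camera with an estimated correlation was run beside it, as was fry, which asks whether the genes of a list move one way without comparing them with other genes. The 33 lists covered cytokines, chemokines, cytotoxic and activation genes, receptors and regulators of signalling, naive and memory genes, zinc finger factors, the cell cycle, metabolism, stress, interferon and NF-kB responses, apoptosis, ribosomal and mitochondrial proteins, and markers of CD8, CD4 and gamma delta T cells, B cells, myeloid cells, NK cells, and platelets and red cells. The design, the lists, the rule for named genes and all alternatives except 3 were fixed before the data were examined.

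Genes named in the text followed a rule. They were the 12 highest and the 12 lowest log2 ratios among genes that passed the threshold with the same sign on all 4 arrays, up to 4 tested members with the smallest p from each list, and a fixed set of genes tied to ILT3, CD8+ T cells and suppression (LILRB4, BCL6, SOCS1, DUSP10, FOXP3, CD8A, CD8B, CD28, IFNG, IL2, GZMB and PRF1). Transcripts without an established name were left out, as were genes whose level can follow a donor's genotype. A further 3 genes that the rule picked are not reported here, and no others took their place.

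The alternatives were Agilent's own log ratio, the authors' value table, a normexp offset of 10, no background correction, median centring in place of loess, scale normalisation after loess, no filter on background, a filter that asked for signal in both channels on all arrays, the mean over all probes of a gene, array weights, no variance moderation, the channels as separate samples without the array as a block, an adjusted p under 0.01, and each array left out in turn. A random block for slide or scan was not run, because the headers gave 1 slide and 1 scan. Centring on the median of the tested genes, averaging arrays 1 to 3 as 1 replicate, and removal of a linear trend on the probes' base counts were added after the data had been seen.

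The fit was tested on simulated data with 18969 genes on 4 arrays, of which 200 were changed, over 20 runs. It recovered 42.7% of genes changed by 0.5 on the log2 scale, 76.4% of those changed by 1 and 93.6% of those changed by 2, and 2.23% of its calls were false. Errors were drawn independently for each gene, and far fewer genes were changed than the 8274 called in the data. These shares need not hold for the data. In 20 further simulated runs camera called a list shifted by 0.5 each time and called 0 of 620 other lists. These runs do not settle the list calls in the data, which depend in part on how far the genes of a list vary together. The correlation estimated there ranged from -0.46 for CD4 T cell markers to 0.85 for type 2 cytokines, and 0 of 32 lists passed with it. Lists with little estimated correlation weakened as well. Unadjusted camera p rose from 0.00153 to 0.0407 for cholesterol synthesis (correlation -0.0034). For naive and memory genes (0.0128) it rose from 0.0170 to 0.102. A call lost in that setting thus does not by itself show that the genes of a list vary together. The number of arrays limits the precision. The labels do not say whether the arrays come from separate cultures or donors, so p-values measure only the spread between these arrays, which may be technical. Figures were drawn with matplotlib 3.10.9.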

Results

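ILT3, encoded by LILRB4, is an inhibitory receptor of antigen-presenting cells, and ILT3-Fc is a soluble fusion of its extracellular part with an immunoglobulin Fc domain. T cells depleted of CD25+ cells were primed for 7 days against allogeneic antigen-presenting cells with or without 50 ug/ml ILT3-Fc and then restimulated for 4 hours with the same presenting cells, after which CD8+ cells were sorted magnetically. RNA of treated and untreated cells was compared directly on each of 4 arrays, so each array gave a ratio. Between 19668 and 23965 of 41000 probes were well above background in Cy3 and between 24764 and 27783 in Cy5, and no spot was saturated. Array 4 stood apart, with a mean Cy3 signal of 507.9 against 1743 to 2112 on the others and a wider spread of log2 ratios (SD 0.73 against 0.41 to 0.53). Across genes, which are not independent replicates, log2 ratios of arrays 1 to 3 correlated with Pearson's r of 0.910 to 0.913 and those of array 4 with them at 0.742 to 0.797.

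The comparison asked which transcripts differed between CD8+ T cells primed with and without ILT3-Fc. In the channel labelled treated, BCL6, a transcriptional repressor of lymphocyte differentiation, had a log2 ratio of -1.38 ± 0.26 (SD, n = 4; limma adjusted p = 0.00171) and was lower on all 4 arrays. This direction, like that of the cytokines below, opposes the published account of the study, in which BCL6 is raised and inflammatory cytokines are reduced by ILT3-Fc. Directions here follow the dye labels throughout. DUSP10, a phosphatase that acts on JNK and p38 kinases, was lower as well at -1.26 ± 0.09, and its other probe gave -1.24. IFNG, the type 1 effector cytokine, was higher at 1.50 ± 0.72, as was IL13 at 1.57 ± 0.67. The lowest ratio among the named genes was that of KLF2, a transcription factor that restrains T cell activation and migration, at -3.28 ± 0.64 or 9.74-fold lower.

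Of 18969 genes tested, 8274 (43.6%) were called, 3762 higher and 4512 lower in the channel labelled treated, and 8255 of these had the same sign on all arrays. With arrays 1 to 3 averaged as 1 replicate beside array 4, limma called 0 genes higher and 0 lower (5914 at an unadjusted p under 0.05). The labels do not say whether these 3 arrays are repeats of the same RNA. At least 2-fold differences numbered 210 higher and 833 lower, and 99 were at least 2-fold higher without array 4, 318 without array 3. Agilent's own log ratio gave 1121 and 2566 such genes. The higher side depended on how the arrays were normalised. When each array was instead centred on the median of all probes, which put the median of the tested genes at -0.24, 1 gene was called higher and 4725 lower (0.0212% higher, against 45.5%), 0 and 2766 of them at least 2-fold. Centred on the tested genes' own median, 1927 were higher and 4820 lower (28.6% higher), 2 and 2093 of them at least 2-fold. Of 83 named genes called higher, 0 stayed called under the first centring and 35 under the second, whereas 50 and 49 of 51 named genes called lower did. Both centrings moved many genes downward, such as the ribosomal proteins (median -0.39 after loess, -1.85 and -1.60 without), so they hardly tested the lower calls. Agilent's own log ratio, which also normalised the dyes, kept 83 of 83 named genes called higher and 48 of 51 called lower. With it 5255 genes were higher and 5241 lower. Without array 2, the array whose removal left the fewest calls, 1578 genes were higher and 2532 lower.

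**Figure D1:**
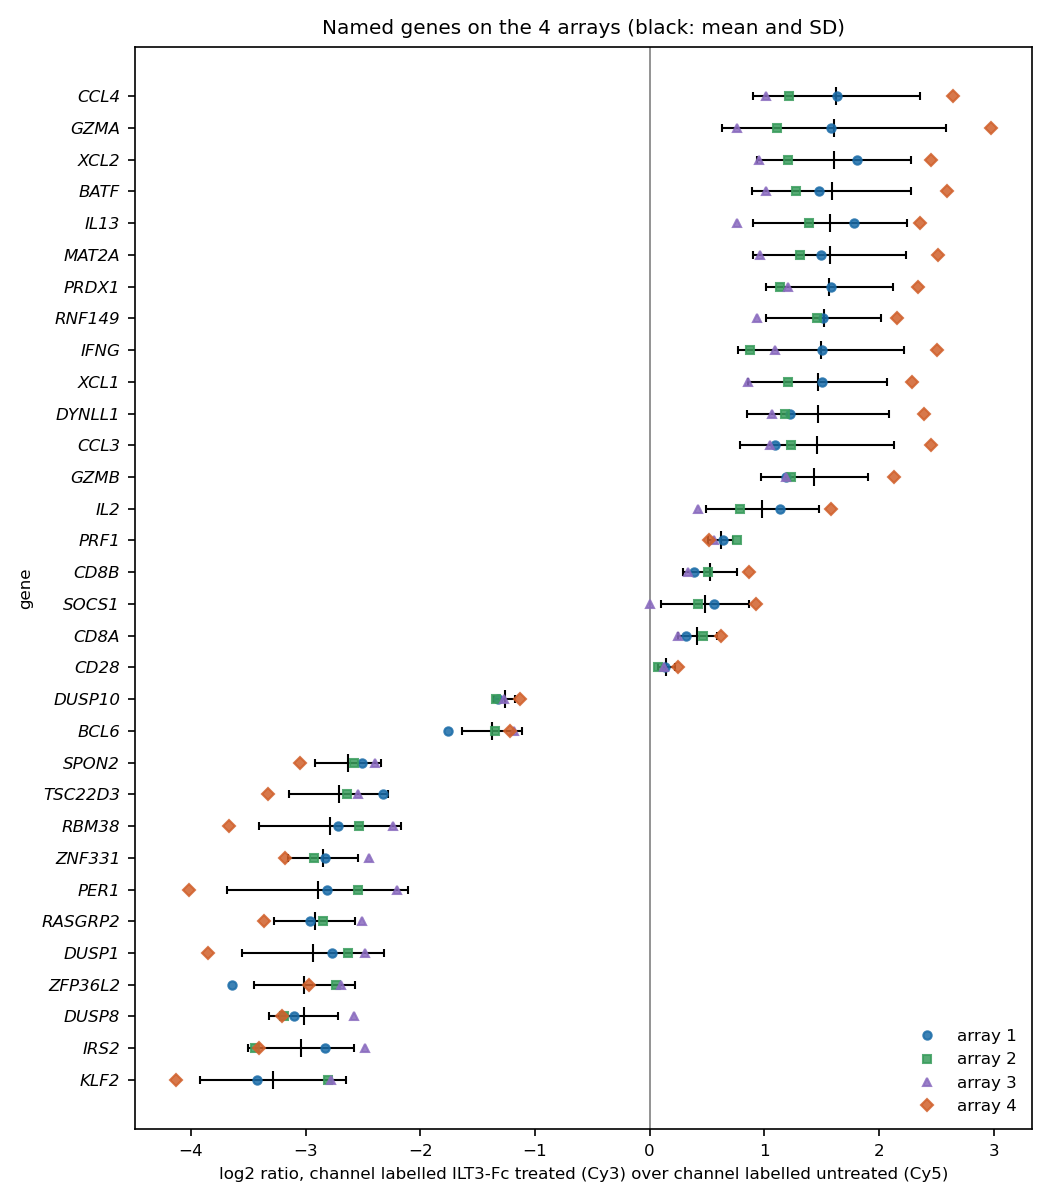
Log2 ratio of the channel labelled ILT3-Fc treated (Cy3) over the channel labelled untreated (Cy5), on the x axis, for the 12 highest, 11 of the 12 lowest and the fixed genes with signal in both channels, 1 per line. Coloured symbols are the 4 arrays and black bars the mean and SD. KLF2 at -3.28 and CCL4 at 1.63 are the extremes; without loess, centred on all probes, CCL3 (-0.06), GZMB (-0.06), PRF1 (-0.08), CD8A (-0.69), CD8B (-0.63), SOCS1 (-0.28) and CD28 (-0.52) turned negative.

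Among the 12 lowest genes were 2 dual-specificity phosphatases that switch off MAP kinases, DUSP8 at -3.02 ± 0.30 and DUSP1 at -2.93 ± 0.62. They also held IRS2, an insulin receptor adaptor, at -3.04 ± 0.47, and ZFP36L2, which destabilises AU-rich mRNAs, at -3.01 ± 0.44. PER1, a circadian clock repressor, had -2.89 ± 0.79, TSC22D3, the glucocorticoid-induced leucine zipper, -2.71 ± 0.43, and RASGRP2, an activator of Rap1, -2.92 ± 0.35. ZNF331 (-2.85 ± 0.30), RBM38 (-2.79 ± 0.62) and SPON2 (-2.63 ± 0.29) were lower too. Adjusted p ranged from 0.00104 for DUSP8 to 0.00296 for PER1, and each of these 11 was lower on all 4 arrays. The rule that picked them required a pass and a shared sign, so neither is a separate result. Other probes of KLF2 (-0.86), IRS2 (nearest to 0 at -0.66) and DUSP8 (nearest to 0 at -0.17) had the same sign but smaller ratios. So did those of RBM38 (-1.35) and PER1 (-2.07), while the other probe of ZNF331 gave -2.88. The KLF2 probe lies on chromosome 19 from 16299246 to 16299305, the BCL6 probe on chromosome 3 from 188922335 to 188922394 and the DUSP10 probe on chromosome 1 from 219941801 to 219941860, in NCBI36 coordinates.

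The 12 highest genes included 4 chemokines. CCL4 (1.63 ± 0.73), XCL2 (1.61 ± 0.67), XCL1 (1.47 ± 0.61) and CCL3 (1.46 ± 0.67) were higher, and CCL3 alone among them turned negative (-0.06) without loess when centred on all probes. IFNG and IL13 also belonged to this set, as did GZMA, a granule protease, at 1.61 ± 0.97 and BATF, an AP-1 factor of effector T cells, at 1.59 ± 0.69. MAT2A, which makes S-adenosylmethionine, had 1.57 ± 0.67, the peroxiredoxin PRDX1 1.57 ± 0.55, RNF149 1.52 ± 0.50 and DYNLL1 1.46 ± 0.62. Their adjusted p ranged from 0.00473 to 0.0234, and each was higher on all 4 arrays, where again the rule required a pass and a shared sign. Each had its highest value on array 4, whose ratios had the widest spread, and a ranking by the mean can favour such genes.

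Effector cytokines and chemokines were higher as groups. Of 12 type 1 and general effector cytokines, 8 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median log2 ratio of 0.83 and a camera adjusted p of 0.00233, and adjusted p = 0.595 with an estimated correlation. The median was 0.45 to 0.61 on arrays 1 to 3 and 1.55 on array 4. TNF (1.39 ± 0.47), IL2 (0.98 ± 0.49) and IFNG were among those higher, and LTB was lower at -0.35 ± 0.12. The other probes of TNF and IL2 gave 0.49 and 0.76. Of 17 chemokines, 13 were higher and 0 lower (13 and 0 adjusted over the list alone; median 0.80, adjusted p = 1.43e-05, and adjusted p = 0.595 with an estimated correlation), including CCL2 at 1.23 ± 0.40 and CCL17 at 1.01 ± 0.37. Myeloid cells also make CCL2 and CCL17, and the myeloid markers C1QA (1.04 ± 0.47), C1QB (1.02 ± 0.37) and CTSB (1.20 ± 0.35) were higher beside them. Of 9 type 2 cytokines and regulators, 6 were higher and 0 lower (6 and 0 adjusted over the list alone; median 0.55, adjusted p = 0.0109, and adjusted p = 0.595 with an estimated correlation), with IL10 at 0.81 ± 0.39 and IL4 at 0.76 ± 0.39. This list's median was 0.22 to 0.49 on arrays 1 to 3 and 1.25 on array 4. Centred on all probes without loess, the medians were 0.18 for type 1 cytokines, 0.14 for chemokines and 0.23 for type 2 cytokines. Type 17 cytokines and regulators did not pass (adjusted p = 0.831; 1 higher and 3 lower of 9, or 2 and 3 adjusted over the list alone). In that list IL17F was higher at 0.33 ± 0.13 and the receptors KLRB1 (-1.87 ± 0.31) and CCR6 (-1.17 ± 0.54) were lower. The list's median was 0.25 and its mean -0.18, with the test pointing upward, and its median was -0.04 when arrays were centred on all probes.

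Genes of T cell activation moved the same way. Of 19 activation and costimulation genes, 14 were higher and 0 lower (15 and 1 adjusted over the list alone; median 0.71, adjusted p = 3e-05, and adjusted p = 0.595 with an estimated correlation), among them TNFRSF9 at 0.83 ± 0.19 and IL2RA, the high-affinity IL-2 receptor chain, at 0.66 ± 0.14. Inhibitory receptors, which are also induced by activation, were 10 higher and 2 lower of 16 (10 and 2 adjusted over the list alone; median 0.41, adjusted p = 0.0286, and adjusted p = 0.595 with an estimated correlation), with HAVCR2 at 1.42 ± 0.38, CD200 at 1.20 ± 0.46, PDCD1 at 1.00 ± 0.43 and, in the other direction, CD5 at -1.62 ± 0.57. Other probes of HAVCR2 gave 0.39 and 0.76. The median of the inhibitory receptors was 0.19 to 0.38 on arrays 1 to 3 and 1.01 on array 4. Genes of regulatory T cells were 6 higher and 1 lower of 12 (7 and 1 adjusted over the list alone; median 0.39, adjusted p = 0.0132, and adjusted p = 0.595 with an estimated correlation). CTLA4 was higher at 0.80 ± 0.35, and TGFB1, a suppressive cytokine, lower at -1.94 ± 0.37. Of the higher members, IL10, TNFRSF18, IL2RA and CTLA4 are also in the type 2, activation or inhibitory receptor lists. Another is also an NF-kB target, so this list is not a result separate from those lists. The regulatory list's median was 0.16 to 0.38 on arrays 1 to 3 and 0.79 on array 4. The inhibitory receptors did not pass without array 4 (adjusted p = 0.0654) or with a linear trend on the probes' base counts removed (adjusted p = 0.0520). The list medians were 0.16 for activation, 0.00 for inhibitory receptors and 0.03 for regulatory T cell genes when centred on all probes. Centred on the tested genes without loess, neither the inhibitory receptors (adjusted p = 0.158) nor the regulatory T cell genes (adjusted p = 0.103) passed. FOXP3 was not well above background on any array and was not tested. LILRB4 was not well above background in Cy3 on any array and was so in Cy5 on 3, so its ratio is not given.

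Cytotoxic effector genes were split, with 8 higher and 4 lower of 18 (9 and 4 adjusted over the list alone), and their median of 0.43 turned to -0.36 and -0.11 under the centrings without loess. By array it was 0.15 to 0.40 on arrays 1 to 3 and 0.73 on array 4. Their adjusted p of 0.0446 was lost with an estimated correlation (adjusted p = 0.595), without array 4 (adjusted p = 0.127) and under both centrings (adjusted p = 0.756 and 0.597). It was also lost with Agilent's log ratio (adjusted p = 0.0802), with signal asked for in both channels (adjusted p = 0.0808), without the array as a block (adjusted p = 0.155) and with the base-count trend removed (adjusted p = 0.0741). GZMB (1.43 ± 0.47), GZMH (0.62 ± 0.09) and PRF1 (0.62 ± 0.11) were higher, but GZMB and PRF1 turned negative when centred on all probes and GZMH under both centrings. ZNF683, a factor of resident and effector memory cells, was lower at -1.57 ± 0.50, and the protease CTSW at -0.99 ± 0.10.

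Immediate early genes did not pass as a list (6 higher, 6 lower of 19, or 8 and 6 adjusted over the list alone; adjusted p = 0.558), with a median of 0.22, a mean of -0.07, a test pointing upward and a median of -0.73 and -0.48 under the centrings. The AP-1 members FOS (-2.48 ± 0.64), JUN (-1.65 ± 0.49) and JUNB (-0.97 ± 0.29) and the nuclear receptor NR4A2 (-1.37 ± 0.07) were lower. Negative regulators of signalling did not pass either (8 higher, 7 lower of 25, or 9 and 8 adjusted over the list alone; adjusted p = 0.93; median 0.03, mean -0.23, test pointing downward, and median -0.32 and -0.07 under the centrings). DUSP1, DUSP10, BCL6 and TNFAIP3, an inhibitor of NF-kB signalling at -2.17 ± 0.28, were lower, whereas SOCS1, an inhibitor of cytokine receptor signalling, had 0.48 ± 0.38, -0.28 and -0.03 under the centrings, and did not pass (adjusted p = 0.0551). CD28, the main costimulatory receptor, did not pass at 0.15 ± 0.07, -0.52 and -0.27 under the centrings (adjusted p = 0.0777).

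Naive and memory T cell genes were lower, with 2 higher and 12 lower of 20 (2 and 12 adjusted over the list alone; median -0.38, and -1.36 and -1.11 under the centrings; adjusted p = 0.0286, and adjusted p = 0.595 with an estimated correlation). Beside KLF2 and BCL6, PIK3IP1, an inhibitor of PI3 kinase, fell by 2.58 ± 0.28 and TXNIP, a negative regulator of glucose uptake, by 1.78 ± 0.20 on the log2 scale. Zinc finger transcription factors of the ZNF, ZBTB, ZKSCAN, ZSCAN and ZFP families were 43 higher and 166 lower of 465 (43 and 167 adjusted over the list alone; median -0.12, and -0.34 and -0.09 under the centrings; adjusted p = 0.00637, and adjusted p = 0.595 with an estimated correlation). ZNF394 was lower at -1.70 ± 0.09, as was ZFP36 at -2.57 ± 0.20. The list took in ZFP36 by its symbol, although it encodes an RNA-binding protein that destabilises cytokine mRNAs. Ribosomal proteins were 2 higher and 47 lower of 80 (2 and 49 adjusted over the list alone; median -0.39, adjusted p = 1.25e-08, and adjusted p = 0.595 with an estimated correlation), with RPL13 at -0.87 ± 0.13 and RPL22 at -0.84 ± 0.10. Under each centring 78 ribosomal protein genes were lower, with medians of -1.85 and -1.60. With Agilent's own log ratio the zinc finger list (adjusted p = 0.0831) and the ribosomal list (adjusted p = 0.314) did not pass. Under the centrings the zinc finger list did not pass (adjusted p = 0.0566 and 0.202). After scale normalisation between arrays the naive and memory list did not pass (adjusted p = 0.144).

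Transcripts of proliferation were higher. Of 24 genes of DNA replication and S phase, 18 were higher and 0 lower (20 and 0 adjusted over the list alone; median 0.44, adjusted p = 2.51e-07, and adjusted p = 0.434 with an estimated correlation), with TK1, thymidine kinase, at 1.32 ± 0.17 and CDC45, a helicase subunit, at 0.96 ± 0.02; the median was -0.08 when centred on all probes. Of 24 mitosis genes, 19 were higher and 1 lower (21 and 2 adjusted over the list alone; median 0.46, adjusted p = 3.39e-06, and adjusted p = 0.595 with an estimated correlation), including BIRC5 at 1.15 ± 0.21 and PLK1 at 0.67 ± 0.17, and with a median of 0.16 when centred on all probes. The other probe of PLK1 gave 0.18.

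Of 4 metabolic lists 3 were higher after loess, and none of these passed under either centring without it. Of 18 glycolysis genes, 12 were higher and 0 lower (13 and 0 adjusted over the list alone; median 0.76, adjusted p = 0.000214, and adjusted p = 0.595 with an estimated correlation), with a median of -0.24 and 0.01 under the centrings. ENO1 (1.34 ± 0.16), PKM (0.82 ± 0.09) and GAPDH (0.95 ± 0.07) were higher, and GAPDH turned negative under both centrings. Oxidative phosphorylation genes were 49 higher and 2 lower of 74 (52 and 2 adjusted over the list alone; median 0.41, adjusted p = 1.68e-12, and adjusted p = 0.434 with an estimated correlation), with a median of -0.45 and -0.20 under the centrings. UQCRQ at 0.86 ± 0.08 and NDUFB8 at 0.82 ± 0.07 also turned negative under both. Cholesterol synthesis genes were 11 higher and 1 lower of 20 (12 and 1 adjusted over the list alone; median 0.32, and -0.19 and 0.06 under the centrings; adjusted p = 0.00444, and adjusted p = 0.434 with an estimated correlation), with NSDHL at 0.33 ± 0.05 and ACAT2 at 0.72 ± 0.09. Under the centrings none of the 3 passed (adjusted p = 0.547 and 0.687 for glycolysis, 0.411 and 0.202 for oxidative phosphorylation, 0.264 and 0.492 for cholesterol synthesis). The hypoxia response did not pass (5 higher, 3 lower of 17, the same adjusted over the list alone; adjusted p = 0.234; median 0.17, and -0.28 and -0.03 under the centrings), although AK4 was higher at 1.30 ± 0.29 and KDM3A lower at -1.23 ± 0.24. The other probe of AK4 gave 0.30, and those of KDM3A gave -1.29 and -0.82.

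Interferon-responsive genes were higher. Of 22 type I interferon response genes, 16 were higher and 0 lower (17 and 0 adjusted over the list alone; median 0.55, 0.01 when centred on all probes; adjusted p = 3.25e-06, and adjusted p = 0.595 with an estimated correlation), with IFI27 at 0.98 ± 0.25 and IFIT1 at 0.58 ± 0.12. Of 19 interferon gamma response genes, 14 were higher and 1 lower (15 and 1 adjusted over the list alone; median 0.71, adjusted p = 9.97e-06, and adjusted p = 0.595 with an estimated correlation), with the immunoproteasome subunits PSMB10 at 1.19 ± 0.26 and PSMB9 at 0.96 ± 0.04 and the peptide transporter TAP1 at 1.14 ± 0.31. The median (-0.01) and TAP1 (-0.10) turned negative when centred on all probes. Of 17 NF-kB targets, 10 were higher and 2 lower (10 and 2 adjusted over the list alone; median 0.35, -0.10 when centred on all probes; adjusted p = 0.0197, and adjusted p = 0.595 with an estimated correlation), with TRAF1 at 0.86 ± 0.34 and NFKBIZ at -1.08 ± 0.34. Their median was 0.25 to 0.35 on arrays 1 to 3 and 0.79 on array 4. The NF-kB targets did not pass under the centrings (adjusted p = 0.863 and 0.921).

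Stress-related lists gave mixed results. Heat shock proteins were 9 higher and 3 lower of 13 (9 and 3 adjusted over the list alone; adjusted p = 0.0288, and adjusted p = 0.595 with an estimated correlation), with a median of 0.66 (0.49 to 0.54 on arrays 1 to 3 and 1.07 on array 4) that turned to -0.30 and -0.05 under the centrings. HSPA8 (1.18 ± 0.37) was higher but negative when centred on all probes, and DNAJB1 (-1.75 ± 0.32) was lower. Genes of the integrated stress and unfolded protein response were 8 higher and 1 lower of 19 (9 and 1 adjusted over the list alone; adjusted p = 0.0197, and adjusted p = 0.595 with an estimated correlation), with a median of 0.52 (0.26 to 0.30 on arrays 1 to 3 and 1.04 on array 4) that turned to -0.45 and -0.20. The amino acid synthesis gene PSAT1 (1.06 ± 0.43) and the ATF4 target TRIB3 (1.19 ± 0.32) were higher, while the transcription factor DDIT3 was lower at -0.82 ± 0.38. The other probe of TRIB3 gave 0.25. The second list did not pass without array 4 (adjusted p = 0.0543). Under the centrings neither the heat shock list (adjusted p = 0.583 and 0.620) nor the stress response list (adjusted p = 0.863 and 0.721) passed. Apoptosis regulators did not pass (4 higher, 5 lower of 17, or 5 and 5 adjusted over the list alone; adjusted p = 0.93; median 0.08, mean -0.06, test pointing upward, and median -0.60 and -0.35 under the centrings). CASP8 (-0.78 ± 0.22) and BIRC2 (-0.71 ± 0.11) were lower.

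**Figure D2:**
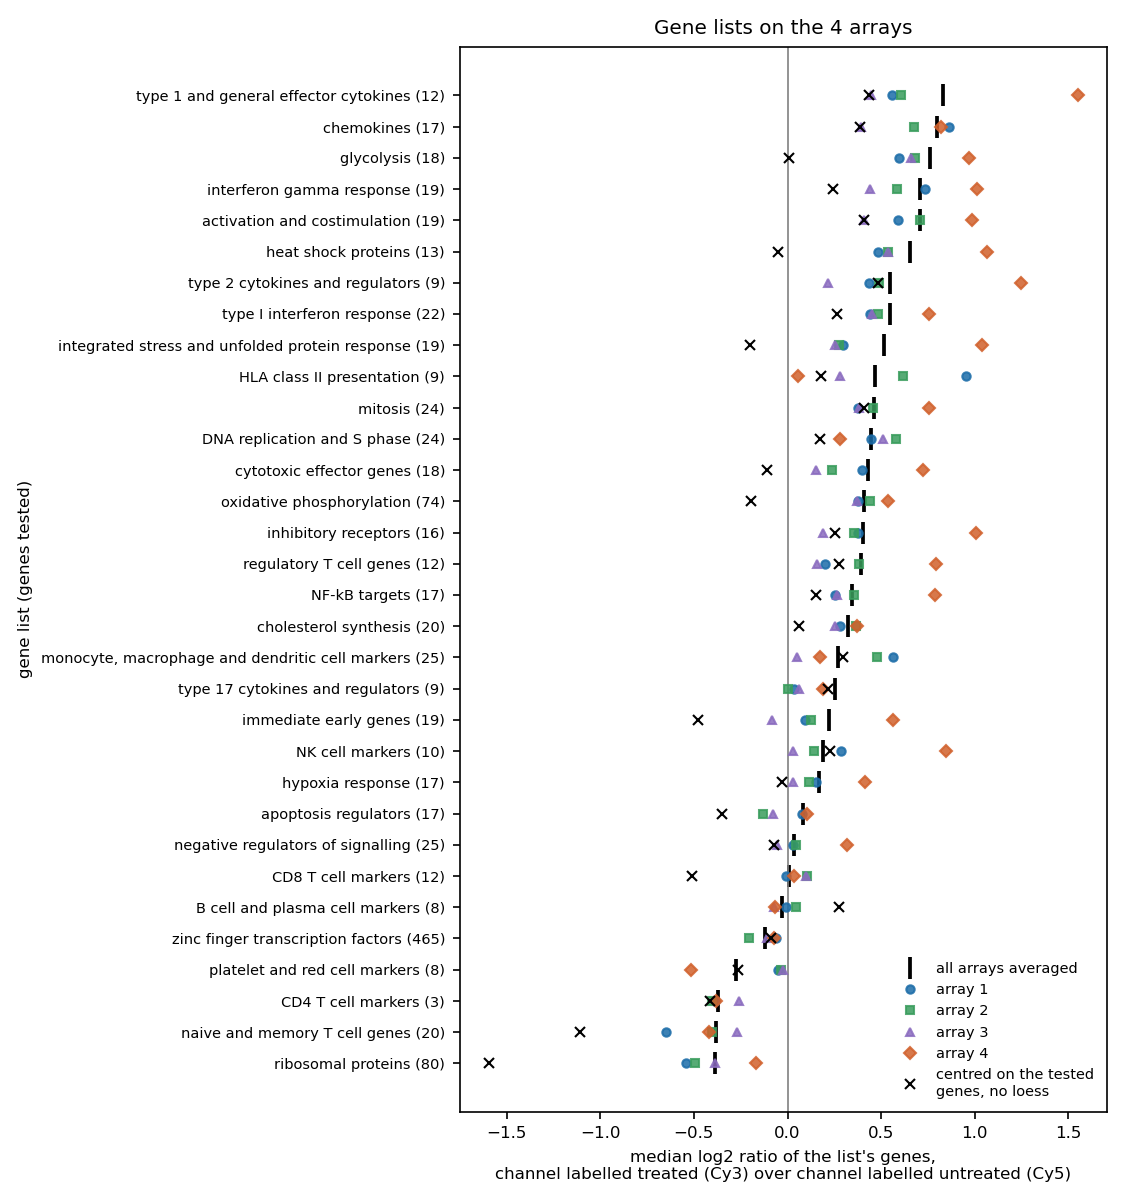
Median log2 ratio of the channel labelled treated (Cy3) over the channel labelled untreated (Cy5), on the x axis, for the 32 gene lists, with the number of genes tested in brackets. Coloured symbols are the 4 arrays, the black bar the median of the gene means over arrays and the cross the same median when arrays were centred on the tested genes without loess. Type 1 cytokines (0.83) and ribosomal proteins (-0.39) are at the ends, and the crosses of CD8 T cell markers (-0.51), immediate early genes (-0.48), apoptosis regulators (-0.35), oxidative phosphorylation (-0.20), the integrated stress response (-0.20), cytotoxic genes (-0.11), negative regulators (-0.07), heat shock proteins (-0.05), hypoxia (-0.03) and B cell markers (0.28) lie on the other side of 0.

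Markers of the cells in or near the sort were measured too. CD8 T cell markers did not pass as a list (5 higher, 3 lower of 12, the same adjusted over the list alone; adjusted p = 0.742), with a median of 0.01 that was -0.76 and -0.51 under the centrings, and lower with adjusted p = 0.0269 under the second. CD8A (0.41 ± 0.17) and CD8B (0.53 ± 0.24) were higher after loess but negative under both centrings, and the other CD8B probe gave -0.48. The signalling chains CD3E (-0.65 ± 0.10) and CD247 (-0.83 ± 0.17) were lower. The 3 CD4 T cell markers did not pass by camera (0 higher, 2 lower, the same adjusted over the list alone; adjusted p = 0.354; median -0.37, and -0.67 and -0.42 under the centrings), with CD4 at -0.51 ± 0.13. CD40LG went the other way at 0.55 ± 0.67 without passing (limma adjusted p = 0.137), and the mean of this list was -0.11. Fry, which makes no comparison with other genes, called the CD4 list lower (fry adjusted p = 0.0028). Monocyte, macrophage and dendritic cell markers, which antigen-presenting cells express, were 9 higher and 1 lower of 25 (9 and 1 adjusted over the list alone; median 0.27, 0.05 when centred on all probes; adjusted p = 0.0132, and adjusted p = 0.595 with an estimated correlation), with the complement genes C1QA at 1.04 ± 0.47 and C1QB at 1.02 ± 0.37 higher and S100A9 at -0.54 ± 0.12 lower. The median of this list was 0.57, 0.48, 0.05 and 0.17 on arrays 1 to 4, and that of HLA class II genes 0.95, 0.62, 0.28 and 0.05. HLA class II presentation genes were 3 higher and 0 lower of 9 (3 and 0 adjusted over the list alone; median 0.47, -0.07 when centred on all probes; adjusted p = 0.0478, and adjusted p = 0.595 with an estimated correlation), with HLA-DMB at 1.07 ± 0.48. They did not pass without array 1 (adjusted p = 0.0714), without array 2 (adjusted p = 0.110) or under the centrings (adjusted p = 0.252 and 0.434). The class II call was also lost with Agilent's log ratio (adjusted p = 0.0696), scale normalisation (adjusted p = 0.109), signal asked for in both channels (adjusted p = 0.0786), no block (adjusted p = 0.0804), arrays 1 to 3 averaged (adjusted p = 0.0805) and the base-count trend removed (adjusted p = 0.0854). The myeloid list did not pass after scale normalisation between arrays (adjusted p = 0.0594) or without the array as a block (adjusted p = 0.0654). B cell and plasma cell markers (1 higher, 1 lower of 8; adjusted p = 0.93; median -0.03, and 0.03 and 0.28 under the centrings), NK cell markers (4 higher, 1 lower of 10; adjusted p = 0.184; median 0.19, 0.03 to 0.29 on arrays 1 to 3 and 0.85 on array 4, -0.02 when centred on all probes) and platelet and red cell markers (0 higher, 1 lower of 8, 0 and 0 adjusted over the list alone; adjusted p = 0.588; median -0.28) did not pass. The counts of the first 2 were the same adjusted over the list alone. NK cell markers passed as higher with arrays 1 to 3 averaged (adjusted p = 0.0466). No gamma delta T cell marker was tested.

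**Figure D3:**
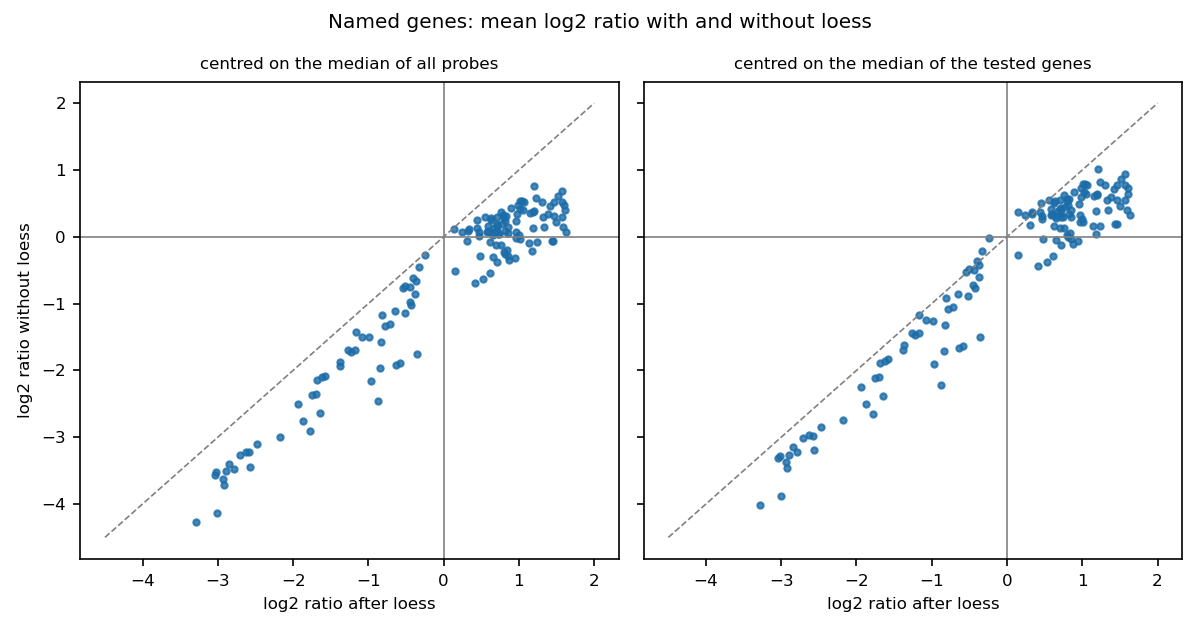
Mean log2 ratio of the named genes except LILRB4, Cy3 over Cy5, after loess on the x axis and without loess on the y axis, with arrays centred on all probes at the left and on the tested genes at the right. Points are genes and the dashed line marks equal values. All 51 genes called lower stayed below 0 in both, whereas 22 of the 83 called higher fell below 0 at the left and 9 at the right. Dropping loess moved many genes downward, so staying below 0 hardly tests the lower calls.

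By camera with the preset correlation, 19 lists were higher and 3 lower, and array 4 had the highest median in 15 of the 19. Of the 32 lists 0 passed with an estimated correlation, where adjusted p ranged from 0.434 to 0.964. Fry called 13, among them the CD4 T cell markers as lower, which camera did not call. Of the lists called by camera, fry did not call type 1 (fry adjusted p = 0.0613) and type 2 cytokines (0.0654), inhibitory receptors (0.0714) and heat shock proteins (0.132). Nor did it call regulatory T cell genes (0.135), myeloid markers (0.135), the integrated stress response (0.154), cytotoxic genes (0.193), NF-kB targets (0.281) and HLA class II genes (0.281). The 4 arrays shared 1 dye orientation, so a treatment effect and a dye effect of the same transcript were not separated.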

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

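Of the tests in this part, the one on the dye labels and the removal of the base-count trend were chosen only after the result was seen. Of 182 groups of 4 arrays examined, 17 held 1 array whose gap to the others passed Dixon's 95% critical value, which chance gives for about 1 group in 20, and 15 of the 17 were array 4.

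On array 4, DYNLL1 had a log2 ratio of 2.39 (1.06 to 1.23 on the others), CCL3 2.46 (1.05 to 1.23), GZMB 2.13 (1.19 to 1.23), IL10 1.40 (0.58 to 0.65), CTLA4 1.32 (0.56 to 0.67), CD40LG 1.55 (0.16 to 0.28) and KLRC3 1.25 (0.31 to 0.44). On the lower side stood FOS at -3.42 (-2.25 to -2.11), CASP8 at -1.11 (-0.71 to -0.65) and PF4 at -1.45 (-0.32 to -0.10). List medians apart on array 4 were those of type 1 cytokines at 1.55 (0.45 to 0.61), heat shock proteins at 1.07 (0.49 to 0.54), the integrated stress response at 1.04 (0.26 to 0.30), type I interferon response genes at 0.75 (0.44 to 0.48) and platelet and red cell markers at -0.52 (-0.05 to -0.03). DUSP8 stood apart on array 3 at -2.58 (-3.20 to -3.11), and RPL7 on array 2 at -0.70 (-0.55 to -0.54). In data that the report does not use, the E1A spike-in controls had a median log2 Cy3 over Cy5 of 4.64 on the array where it was lowest and 6.11 where it was highest.

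Array 4 stood apart in most of these results and had the lowest Cy3 signal. Noise of dim genes is argued against, since among the 4743 brightest genes the lowest correlation of array 4 with another array was 0.763, against a lowest value of 0.925 among arrays 1 to 3. Uneven hybridization is argued against too, since the SD between replicate spots of 222 probes on array 4 was 0.109 of the SD of its difference from the other arrays (0.0516 against 0.472). A separate culture or donor for array 4 stays open, because the labels do not say which arrays share one, and no biological explanation was tested.

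The genes called between the channels might come from the dyes, since all arrays had 1 orientation. A dye effect of single probes is argued against as the whole cause, since 85.7% of the other probes of called genes (3317 of 3870, 95% interval 84.6 to 86.8) had the same sign, and 91.0% of called genes were still called with the same sign once a linear trend on the probes' base counts was removed. A dye effect shared by all probes of a transcript stays open, as does the treatment itself. The 8 orientations of 4 arrays are too few for a share under 0.05, and 1 of them, the real one, called as many as 8274 genes in limma, while the highest of the others called 0 (920 genes at an unadjusted p under 0.05).

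The direction against the published account could come from dyes labelled the wrong way round on all arrays, which cannot be told apart from a true direction by the values. BCL6, at -1.38 as labelled, would be at the same distance above 0 if the labels were exchanged. The deposited value table is also Cy3 over Cy5 and does not settle it, and exchanged labels would turn every direction in the report.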

How the results depend on the processing

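Of the tests in this part, centring on the tested genes, averaging arrays 1 to 3 and removing the base-count trend were chosen only after the result was seen. Of 575 list tests under the alternatives, 482 kept direction and side of the threshold. With the direction kept, 59 lost their call and 1 gained one. A further 33 changed direction, and those that also lost or gained a call are counted only there. Of 2710 gene tests 2253 kept both. With the direction kept, 391 lost their call and 30 gained one, and 36 changed direction, counted in the same way. Of 114 counts 79 stayed within 1.5 times. Agilent's own log ratio and the authors' value table hold the same values, so these totals count that setting once for each and not as independent settings.

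Agilent's own log ratio and the authors' deposited value table each gave 1121 genes at least 2-fold higher, 2566 at least 2-fold lower and 1 list lower. No background correction gave 1431 at least 2-fold lower, array weights 121 at least 2-fold higher, and no variance moderation 1272 higher, 1896 lower and 73 at least 2-fold higher. Channels as separate samples without a replicate block gave 1553 higher and 2762 lower, and an adjusted p under 0.01 gave 1430 and 2218. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry called 13. With arrays 1 to 3 averaged, limma called 0 genes higher and 0 lower, 0 and 0 of them at least 2-fold, with 5914 at an unadjusted p under 0.05; this leaves 2 values per gene. With each array left out in turn, 1578 to 4541 genes were higher, 2532 to 5425 lower and 99 to 318 at least 2-fold higher. Among the called 0 changed sign, which tests little. For 8255 of the 8274 called genes the sign was the same on all arrays, so leaving 1 out could not turn it. Apart from averaging and the stricter threshold, the cause was not tested.

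Median centring in place of loess gave 1 gene higher, 0 at least 2-fold higher, 2766 at least 2-fold lower and 11 lists higher, in limma, with 7366 genes at an unadjusted p under 0.05. Under it CCL3 (-0.0639), IL32 (-0.0242), GZMH (-0.54), PRF1 (-0.0827), GAPDH (-0.32), ALDOA (-0.37), FDPS (-0.13), HSPE1 (-0.35), HSPA8 (-0.22), HSP90AB1 (-0.30), TAP1 (-0.10), NFKB2 (-0.0701), UQCRQ (-0.28), NDUFB8 (-0.25), ATP5MK (-0.19), UQCR11 (-0.22), CD2 (-0.0850), CD8A (-0.69), CD8B (-0.63), HLA-DPA1 (-0.12), HLA-DPB1 (-0.0353), GZMB (-0.0629), SOCS1 (-0.28) and CD28 (-0.52) reversed, the last 2 without a call in either setting. So did the tests, as signed -log10 p, of cytotoxic effector genes (-0.179), heat shock proteins (-0.342) and oxidative phosphorylation (-0.558) and, uncalled in both settings, of immediate early genes (-0.549), apoptosis regulators (-0.842), CD8 T cell markers (-1.40) and B cell markers (0.873).

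Median centring over the tested genes in place of loess gave 1927 higher, 2 at least 2-fold higher, 2093 at least 2-fold lower and 9 lists higher. Under it GZMH (-0.29), GAPDH (-0.0663), ALDOA (-0.12), HSPE1 (-0.10), HSP90AB1 (-0.0484), UQCRQ (-0.0326), NDUFB8 (-0.00327), CD8A (-0.44), CD8B (-0.37), SOCS1 (-0.0328) and CD28 (-0.27) reversed, as did the tests of cytotoxic effector genes (-0.349), heat shock proteins (-0.315), the integrated stress and unfolded protein response (-0.200), NF-kB targets (-0.0473), oxidative phosphorylation (-0.945), immediate early genes (-1.28), the hypoxia response (-0.0357), apoptosis regulators (-1.22), B cell markers (0.748) and CD8 T cell markers (-2.13), the last passing as lower. With the mean over all probes of a gene ALDOA reversed (-0.12), as its other probe gave -0.95 against 0.72 for the brightest. Other changes of direction were all in lists uncalled in both settings. Apoptosis regulators reversed with a normexp offset of 10 (-0.0173), no filter on background (-0.00682), signal asked for in both channels (-0.0256), the mean over all probes (-0.394) and the base-count trend removed (-0.129). B cell markers did with no background correction (0.00817), no replicate block (0.111) and the base-count trend removed (0.270). Type 17 cytokines did with signal asked for in both channels (-0.0507) and no replicate block (-0.230), and negative regulators with scale normalisation (0.163) and arrays 1 to 3 averaged (0.108). With each array left out in turn, negative regulators ranged from -0.227 to 0.0622, apoptosis regulators from -0.0803 to 0.0869 and B cell markers from -0.139 to 0.0512. Apart from ALDOA with the mean over its probes, the cause was not tested for any of these reversals. Signal over background limits LILRB4, which has no usable Cy3 signal, and 64 called genes were well above background in Cy3 on no array. Signal in both channels on all arrays was present for 14152 genes, among which 7576 of the 8274 calls were kept.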

Other observations

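The tests in this part were run on gene lists drawn up after the extremes of the comparison had been seen, leaving out members whose values had been seen by then. MXI1, in the FOXO list, is also in the fixed hypoxia list, and ZBTB16, in the glucocorticoid list, is also in the fixed zinc finger list. The naming rule had picked MXI1 (-1.69), so its value may have been seen. Genes named here outside the rule were chosen after their values were seen.

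Targets of FOXO transcription factors, which act in quiescent T cells and are switched off by PI3 kinase and AKT signalling, were lower in the channel labelled treated. Of 17 targets tested, 12 were lower and 1 higher, with a median log2 ratio of -0.88 (camera adjusted p = 2.97e-05, and adjusted p = 0.232 with an estimated correlation). GABARAPL1, an autophagy gene, had -2.20, GADD45A, a stress-induced growth arrest gene, -1.72 and CDKN1B, the cell cycle inhibitor p27, -1.33, while TRIB1 was higher at 0.87. The median was -1.40 and -1.14 when arrays were centred on all probes and on the tested genes without loess, and the call was kept under both.

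Genes of ribosome biogenesis were higher, although ribosomal protein transcripts were lower. Of 22 tested, 15 were higher and 0 lower, with a median of 0.54 (camera adjusted p = 2.97e-05, and adjusted p = 0.232 with an estimated correlation), but the median was -0.19 when centred on all probes and 0.06 when centred on the tested genes, and the call was lost under both (adjusted p = 0.370 and 0.319). DKC1, a pseudouridine synthase subunit, had 0.80 and NIP7 0.79.

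As a hypothesis, the channel labelled treated may hold the more strongly activated cells, with lower FOXO activity and more ribosome production. The medians of -0.88 and 0.54 went the way this needs, but the second rests on loess, and both were tested on the data in which the pattern was found. Not every list tied to activation went that way. Immediate early genes were 6 higher and 6 lower of 19, with FOS at -2.48 and JUN at -1.65 among the lower. A lower glucocorticoid response, raised by PER1 and TSC22D3 among the lowest genes, was tested as another explanation. The median of 19 other glucocorticoid response genes was -0.0579, with 5 higher and 4 lower (camera adjusted p = 0.525, test pointing upward). Centred on all probes without loess, it was -0.48, with 0 higher and 5 lower (camera adjusted p = 0.526). Centred on the tested genes, it was -0.22, with 1 higher and 5 lower (camera adjusted p = 0.319). Both of these tests pointed downward without passing. A p of 0.05 or more had been set in advance to count against this explanation, but that bound was changed after the result was seen, because members went both ways, from -2.38 for CEBPD to 0.98 for ALOX5AP, and such a median decides nothing. A dye effect shared by all probes of a transcript, and labels exchanged between the dyes, stay open for both lists.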
